A study of Mus musculus with 138 samples.

How the data were processed

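The samples were poly(A) RNA of liver (right medial lobe), muscle (quadriceps femoris) and perigonadal adipose tissue of male CD-1 offspring aged 6 months, from control pregnancies or pregnancies under maternal nutrient restriction (MNR). The labels divide the MNR offspring into tolerant, intolerant and IFBG (impaired fasting blood glucose) animals. RNA was extracted with TRIzol and PureLink columns with DNase treatment and libraries were made with the TruSeq stranded mRNA kit, per the labels' protocols, at one centre for liver and muscle and at another for adipose tissue. In all, 138 samples of 29 animals were used. Intolerant animals 8 and 9 have no liver library here.

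The authors deposited read counts per transcript, whole numbers that were not normalized, in a file per sample. Per the submitters' processing notes, the genome build was mm9 and the tools were FastQC, Bowtie2, DESeq2 and edgeR. Their versions, the counting settings and the use of strand are not given in the sources used here. The files list 95883 mm9 Ensembl transcripts, of which 82946 (86.5%) were matched by identifier to 34030 genes of GENCODE vM21, and 89.0% to 90.5% of each library's reads lay on matched transcripts. Since that annotation is of another build, no coordinates are given, only chromosomes. In 2 rows with no transcript name the counts were 0. Reads of near-identical copies may have been split or shared in the authors' counting, so the Cyp3a, Hspa1a and Hspa1b, serum amyloid, Serpina3 and immunoglobulin genes are uncertain one by one.

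The authors also deposited a merged table per tissue. The values of the liver and muscle tables are counts. The deposited adipose table holds a score, a whole number per gene, and it was not used. Among genes with a single matched transcript and with reads, the score equals the rank of the count sorted as text for 78.1% (median over libraries). In the liver table each of the 27 columns equals the files of its own animal in 71.3% to 71.9% of genes. In the muscle table the 8 control columns equal their own animal's files and all 21 MNR columns equal the files of another MNR animal (71.1% to 72.5% of genes, against at most 1.51% for the named animal), 12 of them of another glucose group. The per-sample files were therefore used throughout, and the merged tables only as an alternative.

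Most liver and muscle libraries were sequenced on 2 lanes, whose counts were summed per animal; each animal counts once. Lanes of a library differed by more than sampling noise, which alone gives about 1 (chi-square per degree of freedom 1.51 to 1.65). Each tissue was analysed alone. Genes were kept with filterByExpr on the 4 groups (15377 in liver, 15856 in muscle and 14586 in adipose tissue), scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (two-sided, robust, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. MNR against control used a factor of 2 levels, and the other comparisons were contrasts of the factor of 4 groups. Differences of the MNR effect between tissues were interaction terms over animals with both tissues. CPM values are scaled by TMM, and log2 CPM used a prior count of 1.

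Gene lists (49, written before the data were examined, as were the groups, the designs and most alternatives) were tested with camera of limma 3.58.1 at its preset correlation of 0.01, where at least 5 genes were measured, with the correlation estimated per list as an alternative. Each list was also scored per animal as the mean of its genes' log2 CPM relative to the tissue mean, and the difference in score was tested by an exact permutation test over all assignments of animals to groups (two-sided, Benjamini-Hochberg over the lists of a tissue and comparison). That score test was chosen after seeing the data. Among the called genes with at least 1 CPM, those named were the 8 with the most positive and the 8 with the most negative fold change (4 and 4 for a glucose group against control), up to 3 called members per list and up to 3 members with the smallest p of a list that passed camera. Where under 6 genes passed, the 4 genes with the smallest p are given as values, and genes of glucose control fixed in advance are given for MNR against control and intolerant against tolerant. Results that need withheld items are not reported.

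Alternatives fixed in advance were DESeq2 1.42.0, RLE scaling, no filter on low counts, limma-voom with and without the file-name code as a random block, the title number as a block, the merged table, the first lane alone, both groups fitted alone, counts summed per file-name code, equal weights of the MNR groups, leaving out animals or control codes, and, for the tissue interactions, the animal as a block. File names carry 4 codes for control and 11 for MNR animals, shared by several animals. The labels do not explain them and they may mark the dam, so p-values treat animals as independent that may share a litter. Alternatives chosen after seeing the data left out libraries with Alb above 500 CPM in muscle (control 6, intolerant 8 and 9), or with Pax8 above 1 or Prm2 above 10 CPM or Alb above 2000 CPM in adipose tissue, left out each animal in 2 adipose comparisons, and used the animal each adipose library matches in muscle. Whether equal title numbers pair animals of different groups was checked, and the numbers did not pair them.

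On simulated counts with 200 changed genes, the MNR test recovered 95% of genes changed 2-fold and 76% of those changed 1.5-fold in liver, 95% and 63% in muscle, and 87% and 58% in adipose tissue, and the intolerant against control test in adipose tissue 81% and 53%. In these simulations the changed genes were drawn from genes above a read threshold, and animals were independent, without shared codes or reads of other tissues. The real tests may therefore recover fewer genes. Reads per library lay between 3856823 and 90394810. The 10 genes with the most reads took 16.1% to 20.8% of reads in liver, 26.2% to 31.5% in muscle and 9.58% to 18.2% in adipose tissue. Correlations and matching used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, with 100000 permutations, and plots matplotlib 3.10.9.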

Results

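Poly(A) RNA of liver, quadriceps muscle and perigonadal fat was sequenced in 29 adult male CD-1 offspring, 6 months old, of control pregnancies or of pregnancies under maternal nutrient restriction (MNR). The MNR offspring were divided by glucose tolerance into tolerant animals, intolerant animals and animals with impaired fasting blood glucose (IFBG). Liver was measured in 8 control, 8 tolerant, 7 intolerant and 4 IFBG animals, and muscle and adipose tissue in 8 control, 8 tolerant, 9 intolerant and 4 IFBG animals. Reads per library ran from 5948287 to 21103749 in liver (median 14420882), from 5412594 to 90394810 in muscle (median 14616274) and from 3856823 to 6879782 in adipose tissue (median 5093902). The coefficient of biological variation between animals was 0.201 in liver, 0.241 in muscle and 0.370 in adipose tissue, the largest spread in adipose tissue. The comparisons asked how each tissue differed after MNR, how each glucose group differed from control, how intolerant differed from tolerant MNR animals, and whether the MNR effect differed between tissues. Log2 fold changes are given ± SE and levels in CPM, counts scaled to library size, as mean ± SD.

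In liver, 3 genes of the Cyp3a family, cytochrome P450 enzymes that oxidise drugs and steroids, rose in MNR offspring. Cyp3a25 on chromosome 5 rose by 0.62 ± 0.10, from 579 ± 82.5 CPM (n = 8) to 891 ± 151 CPM (n = 19), and lay above the control mean in 19 of 19 MNR animals. Cyp3a57 rose by 0.64 ± 0.11 and Cyp3a59 by 0.61 ± 0.11, each above the control mean in 18 of 19 animals. These genes are close copies of each other and their separate values are uncertain. Ank3, which encodes the membrane adaptor ankyrin-G, rose by 0.93 ± 0.17 and Zwint, a kinetochore gene, by 0.53 ± 0.10. Ptch1, the Hedgehog receptor, decreased by 0.58 ± 0.11. Lad1, a basement membrane gene, decreased by 0.77 ± 0.14 to 4.55 ± 1.03 CPM and was below the control mean in 19 of 19 MNR animals. These 7 of 15377 genes passed edgeR's quasi-likelihood test, with adjusted p from 0.00813 (Cyp3a25) to 0.0218 (Ptch1), and 1534 genes had an unadjusted p under 0.05. DESeq2 called 42 genes, the same 7 among them. The count fell to 0 without control animals 2 and 3, which share a file-name code, to 0 without control animals 7 and 8, and to 0 when counts were summed per code. With the code as a random block in limma-voom, 2 genes passed.

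**Figure D1:**
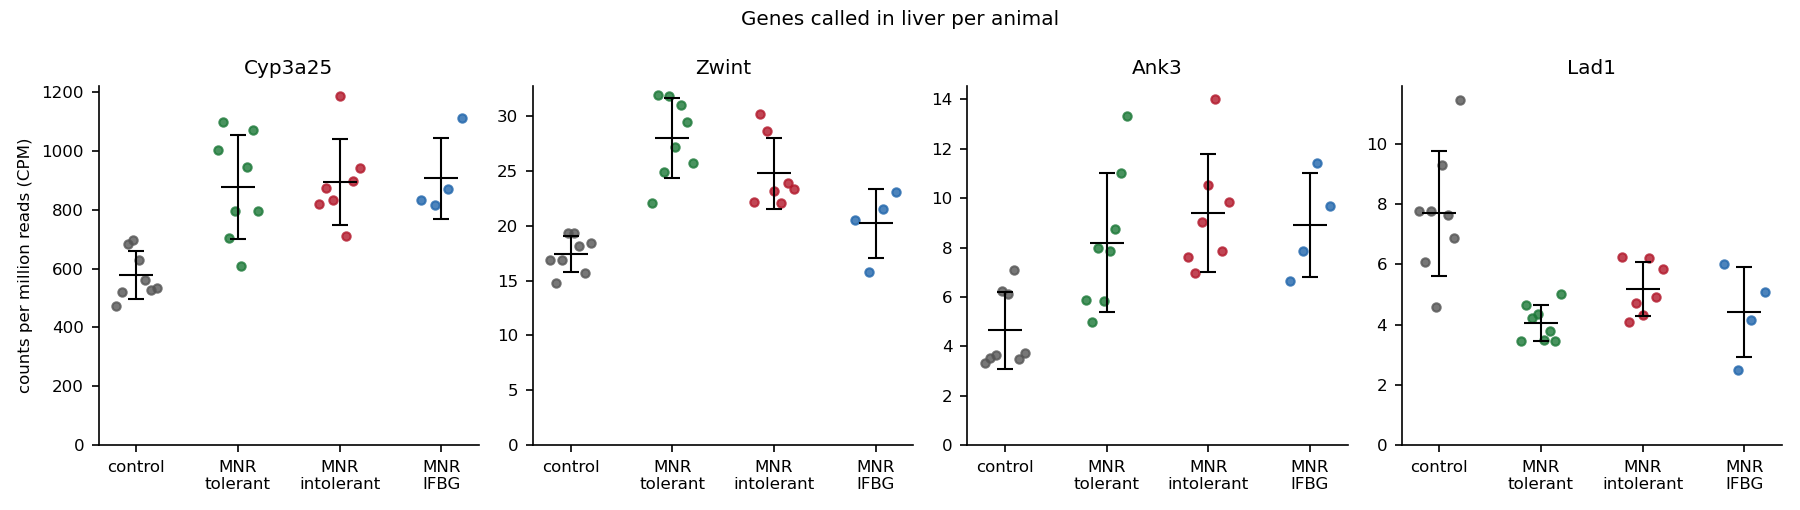
CPM of Cyp3a25, Zwint, Ank3 and Lad1 in liver, one point per animal by group, with the group mean and SD as bars. Cyp3a25 averaged 579 CPM in the 8 control animals and 891 CPM in the 19 MNR animals.

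Among the gene lists fixed in advance, heat shock genes, which encode protein chaperones, had the smallest p in liver. Of 16 measured members, 15 had a negative fold change in MNR offspring, none passed over all genes tested, and 11 fell when adjusted over the list alone. The median log2 fold change was -0.42, and camera gave an adjusted p of 2.1e-12, not kept at an adjusted p = 0.605 with an estimated correlation. Values were -0.64 ± 0.19 for Bag3, a co-chaperone, -0.53 ± 0.15 for Hspa4l and -1.04 ± 0.32 for Hspb1, each with an adjusted p above 0.2 over all genes. Of 23 unfolded protein response genes, 21 lay below 0 (median -0.21, camera adjusted p = 3.9e-05, adjusted p = 0.622 with an estimated correlation), with Chac1 at -0.93 ± 0.35. Lists with a positive median included fatty acid oxidation, with 26 of 33 genes above 0 (adjusted p = 0.637 with an estimated correlation). In oxidative phosphorylation 58 of 66 genes were above 0 (adjusted p = 0.726 with an estimated correlation). Pdk4, an inhibitor of pyruvate dehydrogenase, stood at 1.05 ± 0.35 and Pdhb, a subunit of that enzyme, at 0.32 ± 0.09. Female-biased liver genes had a median of 0.23 (12 of 15 above 0; adjusted p = 0.622 with an estimated correlation), with Cyp2b9 at 2.55 ± 0.84. The oxidative stress gene Gclc, which makes glutathione, stood at 0.35 ± 0.10, the proteasome gene Psmc1 at 0.15 ± 0.04 and the mitochondrial gene mt-Nd6 at 0.27 ± 0.08, none of them past the test over all genes. In all, 12 of 36 lists passed camera with its preset correlation, none with an estimated one. Skeletal muscle transcripts, markers of another tissue, had a median of 0.65 in MNR livers, and Acta1 reached 60.9 CPM in tolerant animal 3 against a median of 21.3 CPM.

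Genes of hepatic glucose control differed by less than the test could call. Insr, the insulin receptor, stood at -0.17 ± 0.05 (94.0 ± 8.59 against 106 ± 8.00 CPM; adjusted p = 0.273 by edgeR) and was lower than the control mean in 16 of 19 MNR animals. G6pc, Pck1, Irs2, Igf1 and Ppargc1a had log2 fold changes of 0.26 ± 0.29, -0.07 ± 0.41, -0.41 ± 0.28, -0.05 ± 0.07 and 0.32 ± 0.26, all with adjusted p above 0.6.

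Set against control, livers of the single glucose groups gave few calls. In tolerant animals Zwint rose by 0.69 ± 0.09, from 17.4 ± 1.65 to 28.0 ± 3.63 CPM with 8 of 8 animals above every control, and Lad1 decreased by 0.95 ± 0.17 (adjusted p = 0.000452 and 0.0316 by edgeR). Both were the sole genes called, DESeq2 called 33 genes and 1458 genes had an unadjusted p under 0.05. Zwint alone (1 gene) passed under limma-voom, in the first lane alone and in the fit of both groups alone, where Lad1 had adjusted p-values from 0.0582 to 0.322. Values in the same livers were 0.60 ± 0.12 for Cyp3a25, 0.25 ± 0.05 for Tspan12 and 0.42 ± 0.10 for Pdhb. Cholesterol synthesis genes had a median of -0.15 with 21 of 23 below 0 (adjusted p = 0.711 with an estimated correlation).

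In intolerant livers every one of the 16 heat shock genes had a negative fold change, and 11 fell when adjusted over the list alone. The mean score of the list, in log2 units, was 0.628 lower in intolerant (-0.270 ± 0.266, n = 7) than in control animals (0.358 ± 0.293, n = 8). Of the 7 intolerant animals 6 lay below every control (exact permutation p = 0.000932, adjusted p = 0.0336 over 36 lists), while camera's call was lost at an adjusted p = 0.272 with an estimated correlation. With means per file-name code as the unit the score difference was -0.539 (exact permutation p = 0.0238), where 5 against 4 codes are too few for 1 list to pass over 36 lists. It passed in 5 of 15 leave-one-out tests, those without control animal 1, 5 or 8 or intolerant animal 1 or 6, and was lost without any other animal, at an adjusted p up to 0.0719. The inducible chaperones Hspa1a and Hspa1b stood at -1.82 ± 0.48 and -1.58 ± 0.47 and Bag3 at -0.74 ± 0.24. Hspa1a and Hspa1b are close copies whose separate values are uncertain. De novo lipogenesis genes had a median of 0.25 with 18 of 22 above 0 (adjusted p = 0.636 with an estimated correlation), and the lipid droplet gene Pnpla3 stood at 1.61 ± 0.58. No gene was called by edgeR (0 of 15377, 1472 with an unadjusted p under 0.05), against 32 by DESeq2, 0 by limma-voom and 10 in a fit of both groups alone. Smallest p-values belonged to Zwint (0.51 ± 0.09), Cyp3a25 (0.63 ± 0.12), Cyp3a57 (0.68 ± 0.14) and Ank3 (1.03 ± 0.21).

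In IFBG livers Cyp3a25 stood at 0.65 ± 0.14, Cyp3a57 at 0.72 ± 0.16, Dnajc12 at 0.94 ± 0.21 and Cyp26b1, a retinoic acid hydroxylase, at -2.36 ± 0.52, with 4 of 4 animals outside the control range for each. Acute phase genes had 22 of 25 members above 0 (median 0.29; 3 rose when adjusted over the list alone; adjusted p = 0.478 with an estimated correlation). Among them were the serum amyloids Saa2 at 3.43 ± 0.77 and Saa1 at 2.70 ± 0.64, close copies of each other, with 2 of 4 animals above the controls. Without IFBG animal 3 they were 0.68 ± 0.64 and 0.80 ± 0.55. Heat shock genes had a median of -0.62 (1 fell when adjusted over the list alone; adjusted p = 0.362 with an estimated correlation), and Hspa4l stood at -0.80 ± 0.24. edgeR called 0 genes, with 892 at an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0.

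Intolerant and tolerant livers gave 0 calls by edgeR, DESeq2 and limma-voom, with 880 genes at an unadjusted p under 0.05. Smallest p-values belonged to 5830473C10Rik (0.68 ± 0.15), Dym (-0.39 ± 0.09), Gm5943 (-0.64 ± 0.16) and Zadh2 (0.23 ± 0.06). Oxidative phosphorylation genes had 60 of 66 members below 0 in intolerant animals (median -0.10; 3 fell when adjusted over the list alone; adjusted p = 0.723 with an estimated correlation), with Ndufs5 at -0.25 ± 0.07. Glucocorticoid response genes had a median of -0.31 with 17 of 19 below 0 (adjusted p = 0.723 with an estimated correlation), with Zbtb16 at -1.62 ± 0.57. For the genes of glucose control, G6pc stood at 0.25 ± 0.35, Pck1 at -0.52 ± 0.51, Irs2 at -0.08 ± 0.37, Insr at -0.01 ± 0.07, Igf1 at 0.11 ± 0.08 and Ppargc1a at -0.32 ± 0.30.

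In muscle, heat shock genes were again the list with the smallest p between MNR and control offspring. All 16 measured members had a negative fold change (median -0.57), and 14 fell when adjusted over the list alone, while none passed over all genes. Hspb1 stood at -0.83 ± 0.20 (102 ± 40.4 against 180 ± 66.3 CPM), below the control mean in 20 of 21 MNR animals, Hsph1 at -0.64 ± 0.18 and Hsp90ab1 at -0.23 ± 0.06. camera gave an adjusted p of 4e-21, and the call was lost at an adjusted p = 0.0687 with an estimated correlation. Fatty acid oxidation genes had 26 of 29 members above 0 (median 0.24; 1 rose when adjusted over the list alone, Slc25a20, the carnitine carrier of mitochondria, at 0.36 ± 0.10; adjusted p = 0.730 with an estimated correlation). Slow fibre genes had a median of 1.73, and 10 of 12 rose when adjusted over the list alone (adjusted p = 0.792 with an estimated correlation). Values were for the slow myosin light chain Myl3 3.11 ± 1.25, for Casq2 0.92 ± 0.37 and for Atp2a2 1.48 ± 0.60. The slow myosin Myh7 ran from a median of 42.3 CPM up to 1336 CPM in intolerant animal 7 and 980 CPM in tolerant animal 1. Mitochondrial mt-Nd6 stood at 0.25 ± 0.09 and the stress transcription factor Atf4 at -0.15 ± 0.05.

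Over all 15856 genes, 0 passed edgeR's test between MNR and control muscle, 1232 had an unadjusted p under 0.05, DESeq2 called 2 genes and limma-voom 2 without and 0 with the block. Smallest p-values belonged to Ahctf1 (-0.30 ± 0.06, adjusted p = 0.146), Chkb, a choline kinase (0.37 ± 0.07), Atp13a5 (-0.82 ± 0.18) and Gm13010 (-2.53 ± 0.57). Genes of muscle glucose uptake were not called. Slc2a4, the insulin-dependent glucose transporter, stood at -0.02 ± 0.05 (381 ± 34.4 against 386 ± 26.3 CPM), Insr at -0.02 ± 0.05, Hk2 at 0.00 ± 0.09, Pdk4 at 0.07 ± 0.33, Ppargc1a at 0.17 ± 0.25 and Irs1 at -0.30 ± 0.16.

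In intolerant muscle the heat shock score was 0.792 lower in intolerant (-0.331 ± 0.332, n = 9) than in control animals (0.462 ± 0.463, n = 8). Of the 9 intolerant animals 7 lay below every control (exact permutation p = 0.00111, adjusted p = 0.0389 over 35 lists). All 16 genes were negative (median -0.82), 15 fell when adjusted over the list alone, and camera passed also at an adjusted p = 0.0293 with an estimated correlation. With means per file-name code the score difference was -0.657 (exact permutation p = 0.0121), where 7 against 4 codes are too few for 1 list to pass over 35 lists. Hsph1 stood at -0.95 ± 0.21, Hspb1 at -1.05 ± 0.23 and Hsp90ab1 at -0.30 ± 0.07. The score test passed in 4 of 17 leave-one-out tests, those without control animal 1, 2 or 4 or intolerant animal 3, and was lost without any other animal, at an adjusted p up to 0.114. Over all genes 2 passed. Cep170, a centrosome gene, decreased by 0.50 ± 0.07 and was below every control in 9 of 9 animals. Gm13010 decreased by 4.55 ± 0.70, from 3.12 ± 1.30 to 0.123 ± 0.0729 CPM (both adjusted p = 0.00328). DESeq2 called 78 genes, limma-voom 1, the first lane alone 0 and a fit of both groups alone 6. Chkb (0.44 ± 0.08) and Dmp1 (-1.19 ± 0.23) were next. Pmp22, a myelin gene, stood at 0.53 ± 0.18. Of 12 nerve and Schwann cell markers 6 rose when adjusted over the list alone (median 0.45; adjusted p = 0.718 with an estimated correlation). Liver transcripts were unequal in these libraries, with Alb at 1689 CPM in intolerant animal 8 and 1317 CPM in intolerant animal 9 against a median of 62.4 CPM.

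**Figure D2:**
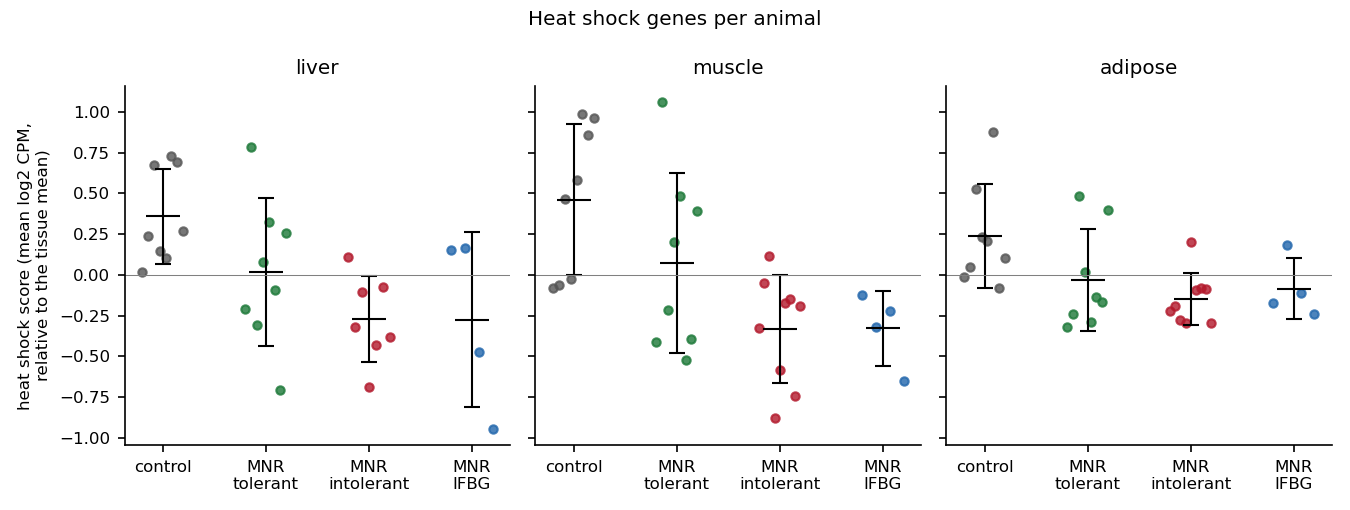
Heat shock score (mean log2 CPM of the list's genes relative to the tissue mean) in liver, muscle and adipose tissue, one point per animal by group, with the group mean and SD as bars. Intolerant animals averaged -0.270 in liver, -0.331 in muscle and -0.148 in adipose tissue, and control animals 0.358, 0.462 and 0.239.

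In tolerant muscle, genes of mitochondrial fuel use lay above control. Of 29 fatty acid oxidation genes, 14 rose when adjusted over the list alone (median 0.31; adjusted p = 0.503 with an estimated correlation), with the acyl-CoA dehydrogenase Acadl at 0.66 ± 0.18, from 177 ± 38.8 to 279 ± 64.8 CPM, and Slc25a20 at 0.46 ± 0.11. All 19 TCA cycle genes were above 0 (adjusted p = 0.503 with an estimated correlation), Idh2 at 0.85 ± 0.30 among them, and 8 of 13 mitochondrially encoded genes rose when adjusted over the list alone (adjusted p = 0.503 with an estimated correlation). Slow fibre genes had a median of 2.02, with 10 of 12 rising when adjusted over the list alone (adjusted p = 0.554 with an estimated correlation). The slow myosin Myh7 stood at 980, 621 and 398 CPM in tolerant animals 1, 6 and 5. In the other tolerant animals it ran from 31.7 to 118 CPM, against up to 157 CPM in controls. Acadl lay above the control mean in 8 of 8 tolerant animals. Whether the fuel genes followed the slow fibre genes was not tested. Over all genes edgeR called 0 (1212 at an unadjusted p under 0.05), DESeq2 6 and limma-voom 0, with Pln, the calcium pump inhibitor of slow fibres, at 1.09 ± 0.22, Supt16 at 0.27 ± 0.06, Abcb8 at 0.29 ± 0.06 and Gm13010 at -2.88 ± 0.61.

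In IFBG muscle 2410002F23Rik rose by 0.74 ± 0.13, from 4.98 ± 0.743 to 8.37 ± 0.818 CPM with 4 of 4 animals above every control (adjusted p = 0.0459), the sole gene called by edgeR. Without any 1 of the IFBG animals 0 genes passed, and 0 passed with RLE scaling, without a count filter, in the first lane alone or in a fit of both groups alone. Values were 0.44 ± 0.10 for Cyb561d1, -0.92 ± 0.23 for the transcription factor Cebpb and -0.84 ± 0.21 for 4933421O10Rik. Heat shock genes had a median of -0.45 (7 of 16 fell when adjusted over the list alone; adjusted p = 0.251 with an estimated correlation), with Dnaja1 at -1.0 ± 0.31. Interferon response genes had a median of 0.39 with 24 of 26 above 0 (adjusted p = 0.251 with an estimated correlation), with Irf7 at 0.68 ± 0.30.

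Intolerant and tolerant muscle gave 0 calls by edgeR, DESeq2 and limma-voom, and 1263 genes had an unadjusted p under 0.05. Uap1 (-0.29 ± 0.06), Foxo3, a transcription factor of the insulin pathway (-0.32 ± 0.07), Pdpk1, a kinase of that pathway (-0.20 ± 0.05), and Eea1 (-0.32 ± 0.08) had the smallest p-values. Insulin signalling genes had a median of -0.05 with 20 of 26 below 0 (2 fell when adjusted over the list alone; adjusted p = 0.625 with an estimated correlation). Cholesterol synthesis genes had a median of 0.18 (adjusted p = 0.641 with an estimated correlation). Slc2a4, Irs1, Insr, Hk2, Pdk4 and Ppargc1a stood at -0.01 ± 0.06, 0.05 ± 0.20, -0.12 ± 0.05, -0.21 ± 0.10, -0.07 ± 0.40 and -0.84 ± 0.24, none with an adjusted p under 0.5.

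Adipose tissue of MNR offspring lay below control in most oxidative and adipocyte genes. Of 67 nuclear oxidative phosphorylation genes, 66 were below 0 (median -0.17) and 7 fell when adjusted over the list alone (adjusted p = 0.240 with an estimated correlation). Of 30 adipocyte genes, 29 were below 0 (median -0.37) and 3 fell when adjusted over the list alone. Their score changed by -0.413 in MNR animals (exact permutation p = 0.00620, adjusted p = 0.0558 over 36 lists; adjusted p = 0.240 with an estimated correlation). Gpihbp1, the endothelial anchor of lipoprotein lipase, stood at -0.56 ± 0.11 (79.2 ± 16.1 against 117 ± 16.9 CPM), below the control mean in 21 of 21 animals. The complex I gene Ndufv3 stood at -0.40 ± 0.08 and Srebf1, a regulator of lipogenesis, at -0.59 ± 0.16. Immediate early genes lay above 0 (median 0.32; 7 of 21 rose when adjusted over the list alone; adjusted p = 0.240 with an estimated correlation), with Fos at 1.05 ± 0.28 and Egr1 at 0.93 ± 0.27. Cell cycle genes were above 0 in 33 of 33 cases (1 rose when adjusted over the list alone, Rrm1 at 0.48 ± 0.11; adjusted p = 0.240 with an estimated correlation). Macrophage genes had a median of 0.91 (2 of 34 rose when adjusted over the list alone; adjusted p = 0.345 with an estimated correlation), with Ccr2 at 1.12 ± 0.34. B and plasma cell genes had a median of 2.32 (10 of 15 rose when adjusted over the list alone; adjusted p = 0.438 with an estimated correlation). The library of intolerant animal 5 held 2543 CPM of Ighg1 against a median of 1.12 CPM.

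Heat shock genes stood lower in MNR fat as well (median -0.24; 6 of 16 fell when adjusted over the list alone; adjusted p = 0.240 with an estimated correlation), with Dnaja1 at -0.42 ± 0.12 and Hspa1a at -1.20 ± 0.34. The mast cell proteases Tpsb2 and Mcpt4 stood at -1.21 ± 0.30 and -1.14 ± 0.29, below the control mean in 20 of 21 animals each. Robo4, an endothelial receptor, stood at -0.38 ± 0.10 in an endothelial list with 18 of 19 genes below 0 (4 fell when adjusted over the list alone; adjusted p = 0.240 with an estimated correlation). The imprinted gene Grb10, an inhibitor of insulin receptor signalling, stood at -0.32 ± 0.07. The single gene past the test over all 14586 genes was AK157302, which decreased by 0.51 ± 0.08, from 27.9 ± 3.48 to 19.6 ± 2.79 CPM with 21 of 21 animals below the control mean (adjusted p = 0.0109). Rbpms stood at -0.42 ± 0.08, and 2390 genes had an unadjusted p under 0.05. DESeq2 called 56 genes and limma-voom 11. edgeR called 0 without the control animals of file-name code 2, 3 or 4, and 0 with counts summed per code. These codes follow the animal numbers as labelled, which matching with muscle puts in doubt for adipose tissue. Without the 2 libraries with the most Alb reads edgeR called 0 genes. Of the genes of glucose and adipokine control, Slc2a4 stood at -0.52 ± 0.16 (adjusted p = 0.184, below the control mean in 21 of 21 animals). Further values were Adipoq at -0.42 ± 0.18, Pparg at -0.35 ± 0.16, Irs1 at -0.28 ± 0.14, Insr at -0.13 ± 0.08 and Lep at 0.31 ± 0.28.

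The adipose tissue of intolerant animals set against control held most calls of the series, 957 genes of 14586 (630 higher and 327 lower), with 3421 at an unadjusted p under 0.05. Of the macrophage genes, 20 of 34 rose over all genes and 27 when adjusted over the list alone (median 1.40; adjusted p = 0.244 with an estimated correlation). The chemokine receptor Ccr2 rose by 1.49 ± 0.35, from 42.9 ± 18.3 CPM (n = 8) to 121 ± 30.1 CPM (n = 9), with 8 of 9 animals above every control (adjusted p = 0.0253). The macrophage marker Adgre1 rose by 1.41 ± 0.34 and the oxidase subunit Cybb by 1.45 ± 0.35. Genes of MHC class II antigen presentation rose with them, 6 of 8 over all genes and 7 when adjusted over the list alone (adjusted p = 0.244 with an estimated correlation). The transactivator Ciita rose by 1.51 ± 0.40, H2-Ab1 by 1.15 ± 0.29 and Cd74 by 1.08 ± 0.29. Cell cycle genes (9 of 33 rose, 19 when adjusted over the list alone; adjusted p = 0.244 with an estimated correlation) included Mcm2 at 0.83 ± 0.19, Tk1 at 0.99 ± 0.27 and Rrm1 at 0.49 ± 0.13. Matrix genes (6 of 38 rose, 14 when adjusted over the list alone; adjusted p = 0.244 with an estimated correlation) included collagen Col1a1 at 0.88 ± 0.25, Col8a1 at 0.57 ± 0.16 and the metalloproteinase Mmp14 at 0.74 ± 0.19. Immediate early genes (6 of 21 rose, 10 when adjusted over the list alone; adjusted p = 0.244 with an estimated correlation) included Fos, up by 1.39 ± 0.30 with 9 of 9 animals above every control, Btg2 by 0.51 ± 0.13 and Egr2 by 1.92 ± 0.51. Of 29 genes of DNA methylation and chromatin 4 rose, as many as when adjusted over the list alone, among them Dnmt1, Tet2 and Tet3 by 0.55 ± 0.14, 0.46 ± 0.11 and 0.50 ± 0.13, while the list did not pass camera (adjusted p = 0.281). The cytokine receptor gene Il7r of lymphocytes rose by 2.00 ± 0.62.

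Genes that fell in intolerant fat included members of the adipocyte and oxidative phosphorylation lists. Of 30 adipocyte genes 5 fell, 15 when adjusted over the list alone (median -0.44; adjusted p = 0.244 with an estimated correlation). Lgals12 decreased by 0.73 ± 0.17 and Adig decreased by 0.78 ± 0.19. Slc2a4, the insulin-dependent glucose transporter, decreased by 0.64 ± 0.19, from 142 ± 23.4 to 91.5 ± 29.6 CPM with 9 of 9 animals below the control mean (adjusted p = 0.0418). Akt2, the insulin-signalling kinase, decreased by 0.45 ± 0.12. Of 67 oxidative phosphorylation genes 9 fell, 31 when adjusted over the list alone (adjusted p = 0.252 with an estimated correlation), Cox6c and Ndufs3 among them at -0.30 ± 0.08 and -0.34 ± 0.09. The lipogenic list (3 of 22 fell, 6 when adjusted over the list alone; adjusted p = 0.326 with an estimated correlation) held the acetyl-CoA carboxylase Acacb at -1.30 ± 0.28 and the transcription factors Srebf1 at -0.71 ± 0.18 and Mlxipl at -0.68 ± 0.19. Imprinted genes (3 of 19 fell, 6 when adjusted over the list alone; adjusted p = 0.244 with an estimated correlation) held Nnat at -1.16 ± 0.26 and Grb10 at -0.33 ± 0.08. Per2, a gene of the circadian clock list, stood at -1.10 ± 0.28, with 9 of 9 animals below every control. The glucocorticoid list (3 of 20 fell, 5 when adjusted over the list alone, adjusted p = 0.244 with an estimated correlation) held Hsd11b1 and Pck1. Hsd11b1, which regenerates active glucocorticoid, decreased by 1.29 ± 0.32 and Pck1, an enzyme of glycerol synthesis in fat, decreased by 1.09 ± 0.34. Heat shock genes (2 of 16 fell, 7 when adjusted over the list alone; adjusted p = 0.244 with an estimated correlation) held Hspa1a at -1.60 ± 0.42 and Dnaja1 at -0.52 ± 0.14. Endothelial Robo4 and Ptprb decreased by 0.52 ± 0.11 and 0.40 ± 0.10, below every control in 9 of 9 animals each (4 of 19 endothelial genes fell, 7 when adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). The largest negative values were S100b at -3.90 ± 0.86, Mrap2 at -3.75 ± 1.07 and Rarres1 at -2.88 ± 0.89, each of which varied widely among controls (S100b from 2.44 to 174 CPM).

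**Figure D3:**
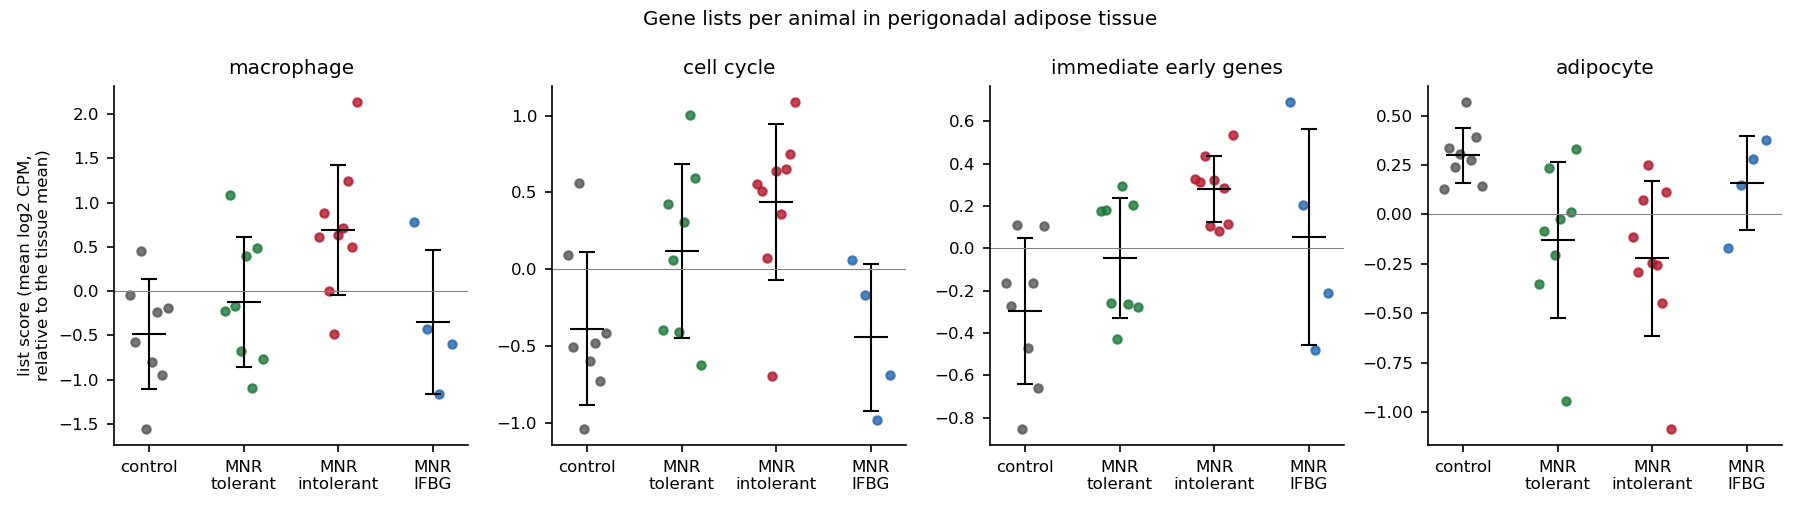
Scores of the macrophage, cell cycle, immediate early and adipocyte gene lists in adipose tissue (mean log2 CPM relative to the tissue mean), one point per animal by group, with the group mean and SD as bars. The macrophage score averaged 0.694 in intolerant and -0.486 in control animals, and the adipocyte score -0.223 and 0.299.

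By exact permutation of animals, 13 of 36 list scores differed between intolerant and control fat. The macrophage score was 1.18 higher (0.694 ± 0.735, n = 9, against -0.486 ± 0.620, n = 8; exact permutation adjusted p = 0.0184), with 7 of 9 animals above every control. The immediate early score was 0.575 higher (exact permutation adjusted p = 0.00889) and the cell cycle score 0.826 higher (exact permutation adjusted p = 0.0305). The adipocyte score changed by -0.522 (exact permutation adjusted p = 0.0148), with 8 of 9 animals below every control, and the heat shock score by -0.386 (exact permutation adjusted p = 0.0184). With an estimated correlation camera gave an adjusted p = 0.244 for each of these 5 lists. Scores of MHC class II (0.978), T and NK cells (0.623), matrix (0.317) and DNA methylation genes (0.150) were higher (adjusted p = 0.244, 0.341, 0.244 and 0.483 with an estimated correlation). Those of the GH and IGF axis (-0.170), oxidative phosphorylation (-0.231), the glucocorticoid response (-0.325) and imprinted genes (-0.228) were lower, all by the same test with adjusted p under 0.05 (adjusted p = 0.326, 0.252, 0.244 and 0.244 with an estimated correlation). With means per file-name code of the matched animals as the unit, 7 against 4 codes, 0 of the 13 passed (exact permutation adjusted p from 0.0545 to 0.212). The smallest p of that test is 0.00303, which 2 lists reached, and 2 lists at that p alone cannot pass over 36 lists. In each of the 17 tests that left out 1 animal, the heat shock, immediate early, macrophage, adipocyte and DNA methylation scores passed. The other 8 were lost in some of them: imprinted genes passed in 12, oxidative phosphorylation and cell cycle in 11 each, matrix in 9, MHC class II in 8, the GH and IGF axis in 7, and T and NK cells and the glucocorticoid response in 5 each. Without the libraries with Pax8 or Prm2 reads 0 of the 13 scores passed (exact permutation adjusted p from 0.0629 to 0.178), with differences of 0.920 for the macrophage and -0.440 for the adipocyte score.

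The number of single genes called moved with the animals in the fit. Without control animals 5, 7, 4, 2, 6 and 8 in turn, edgeR called 0, 18, 20, 378, 592 and 611 genes, and without intolerant animals 9, 7, 2 and 4 in turn 18, 233, 421 and 1734. DESeq2 called 1607 genes, limma-voom 398, a fit without a count filter 402, and a fit without the 7 libraries with Pax8 reads, an epithelial transcription factor, or Prm2 reads, a sperm protamine, 154. A count of 19 passed without the 2 libraries with the most reads of Alb, the albumin gene of liver, (tolerant animal 1 and control animal 7). With the title number as a block, 9 genes passed, and 0 passed with a random block for the file-name code of the animal each library matched in muscle. The 2 immunoglobulin genes with the largest increases, Ighg1 (8.23 ± 1.85) and Ighg2c (8.00 ± 1.69), rested mostly on 1 library, intolerant animal 5, at 2543 and 1726 CPM, without which they were 1.04 ± 0.81 and 2.56 ± 0.81, and their reads can be shared among gene copies.

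**Figure D4:**
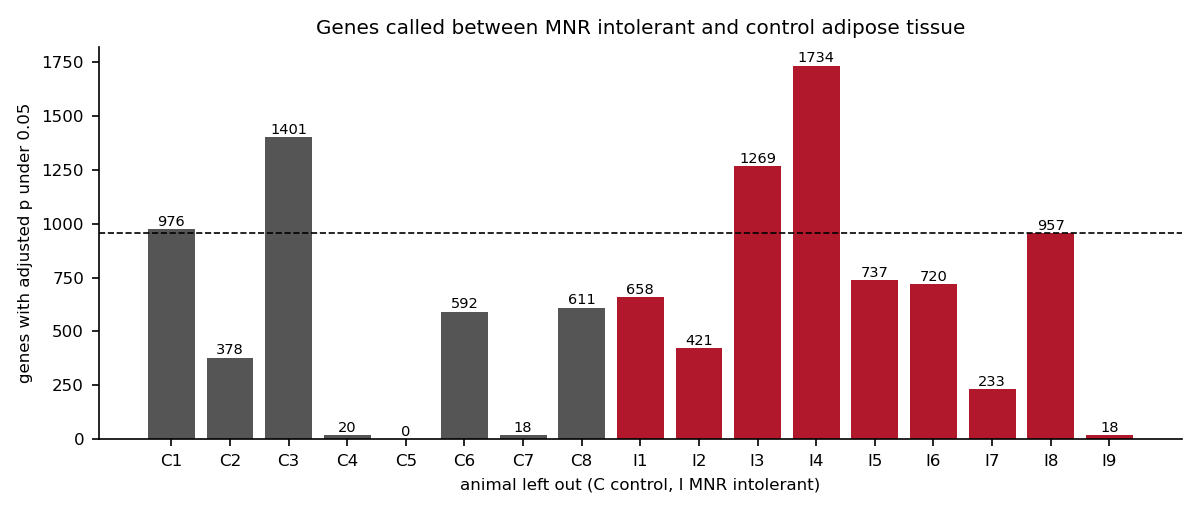
Number of genes with an adjusted p under 0.05 (edgeR) between intolerant and control adipose tissue when the animal on the x axis was left out, as bars from 0. The dashed line marks the 957 genes called with all animals, and the count ran from 0 without control animal 5 to 1734 without intolerant animal 4.

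In tolerant fat no gene was called against control. Values were -0.68 ± 0.18 for Srebf1, -0.96 ± 0.27 for Nnat, -0.37 ± 0.08 for Grb10, 0.50 ± 0.13 for Rrm1 and -0.47 ± 0.10 for AK157302, each in the same direction in 8 of 8 animals. The adipocyte list had 27 of 30 genes below 0 (median -0.37; 1 fell when adjusted over the list alone; exact permutation p = 0.00404 for the score, adjusted p = 0.145; adjusted p = 0.273 with an estimated correlation). Smallest p-values belonged to Ccdc69 (-0.86 ± 0.16), the epithelial protease St14 (2.34 ± 0.45) and Wwp2 (0.53 ± 0.11). Pax8 or Prm2 reads marked 4 of the 8 tolerant libraries and 1 of the 8 control libraries. Without them the median of the adipocyte list was -0.25, and St14 stood at 1.53 ± 0.425. edgeR called 0 genes, with 2275 at an unadjusted p under 0.05, DESeq2 called 184, limma-voom 0 and the fit with the title number as a block 5.

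In IFBG fat, interferon response genes had 30 of 31 members above 0 (median 0.76), and 11 rose when adjusted over the list alone (adjusted p = 0.522 with an estimated correlation). The guanylate-binding genes Gbp11, Gm43302 and Gbp2 stood at 2.49 ± 0.53, 2.66 ± 0.55 and 1.54 ± 0.37 and the chemokine Cxcl10 at 2.93 ± 0.64, with 2 of 4 animals above every control for each. Ptx3, an inflammatory pentraxin, stood at 4.89 ± 0.94 with 2 of 4 animals above every control and up to 173 CPM, and Serpina3h, a member of a family of close copies, at 2.87 ± 0.61 with 1 of 4. These values rested on 1 library: without IFBG animal 1 they were 0.43 ± 0.40 for Gbp11, 0.46 ± 0.41 for Gm43302, 0.30 ± 0.27 for Gbp2, 0.42 ± 0.52 for Cxcl10, 0.49 ± 0.79 for Ptx3 and -0.13 ± 0.395 for Serpina3h. B and plasma cell genes had a median of 2.89 (11 of 15 rose when adjusted over the list alone; adjusted p = 0.389 with an estimated correlation), with Cr2 at 4.37 ± 1.40, above every control in 4 of 4 animals. Immediate early genes held Ier3 at 1.37 ± 0.35 (4 of 21 rose when adjusted over the list alone, adjusted p = 0.389 with an estimated correlation). Without IFBG animal 1 Cr2 and Ier3 were 3.19 ± 1.49 and 0.78 ± 0.34. edgeR called 0 genes, with 898 at an unadjusted p under 0.05, DESeq2 called 12 and limma-voom 0, while leaving out IFBG animal 3 gave 11 calls and leaving out IFBG animal 4 gave 7.

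Intolerant and tolerant fat differed in 274 genes by edgeR (15 higher and 259 lower in intolerant animals), with 2610 at an unadjusted p under 0.05. The genes with the most negative values included epithelial genes: Cuzd1 at -8.24 ± 1.66, Prom2 at -7.44 ± 1.57, Ptgds at -7.32 ± 1.39, Cdh16 at -7.27 ± 1.5, Pou3f3 at -6.91 ± 1.5 and Pax8 at -6.22 ± 1.47. They were carried by few tolerant libraries. Cuzd1 stood at 1633 CPM in tolerant animal 6, 130 CPM in animal 4 and 78.5 CPM in animal 1 against a median of 0.224 CPM, and Pax8 stood at 108, 49.3 and 34.2 CPM in the same animals. Keratins Krt8 (-2.47 ± 0.63) and Krt18 (-2.58 ± 0.62), Mal (-3.95 ± 0.88), Acot1 (-2.03 ± 0.50) and Fads2 (-1.67 ± 0.42) followed them. Without the libraries with Pax8 or Prm2 reads Krt8, Krt18 and Fads2 changed sign, to 0.73 ± 0.56, 0.71 ± 0.53 and 0.45 ± 0.22. Genes that rose were Trip13, a meiosis and spindle checkpoint gene (1.42 ± 0.34, with 9 of 9 animals above the tolerant mean), Pik3ap1 (1.36 ± 0.36) and Gcnt1 (0.68 ± 0.18). Without the libraries with Pax8 or Prm2 reads they were 1.08 ± 0.43, 1.00 ± 0.42 and 0.40 ± 0.185. Ighg1 (7.16 ± 1.71) and Ighg2c (5.77 ± 1.42) also rose, and without intolerant animal 5 were -0.04 ± 0.77 and 0.28 ± 0.72. Macrophage genes had 32 of 34 members above 0 (median 0.92, adjusted p = 0.632 with an estimated correlation). Among them Adgre1 stood at 0.91 ± 0.33, and at 0.13 ± 0.30 without the libraries with Pax8 or Prm2 reads. MHC class II genes had a median of 0.71 (6 of 8 rose when adjusted over the list alone, adjusted p = 0.632 with an estimated correlation). Ciita stood at 1.04 ± 0.40, and at 0.57 ± 0.485 without the same libraries. Adipoq, Lep, Pparg, Slc2a4, Irs1 and Insr stood at -0.03 ± 0.21, 0.34 ± 0.27, 0.18 ± 0.19, -0.15 ± 0.19, 0.07 ± 0.16 and -0.09 ± 0.08.

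No gene passed in that comparison without the libraries with Pax8 or Prm2 reads (0 genes), without those with the most Alb reads (0), in limma-voom (0), or in a fit of both groups alone (0). The count was also 0 without any 1 of intolerant animals 1, 2, 4, 5, 6, 7 and 8 and tolerant animals 1, 4 and 6. The count was 144 without intolerant animal 9, 159 without intolerant animal 3, and 460, 541, 543 and 728 without tolerant animals 3, 5, 7 and 2, and DESeq2 called 397.

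The MNR effect itself differed between tissues for 2 genes. The effect on Ank3 was 1.06 ± 0.17 larger (log2) in liver than in muscle (adjusted p = 0.00132 over 14031 genes), a call lost with the animal as a block (adjusted p = 0.159), and DESeq2 called 66 genes. AK157302 had an effect 0.49 ± 0.09 larger in muscle than in adipose tissue, where it fell (adjusted p = 0.0208 over 13373 genes). With the animal as a block the adjusted p was 0.0152 with adipose animals numbered as labelled, and the call was lost with each adipose library given the animal it matched in muscle (0.49 ± 0.09, adjusted p = 0.120, 0 genes called). DESeq2 called 13 genes. Between liver and adipose tissue edgeR called 0 of 12878 genes, with 1517 at an unadjusted p under 0.05, and DESeq2 called 10. Muscle and liver libraries were made at one centre and adipose libraries at another, so the tissues themselves were not compared.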

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

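Of the tests in this part, those of the muscle table over the most variable genes were planned before the result was seen. The matching of adipose libraries over odd and even chromosomes was also written down before its result. Those of the correlation within codes in adipose tissue, the heat shock genes, the macrophage and adipocyte genes and the other splits were chosen only after the results were seen.

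All 21 MNR columns of the merged muscle table held counts of another MNR animal. If the per-sample muscle files carried the wrong animals, they would not match the liver of the same animal. Yet 16 of 27 animals, 9 of the 19 MNR animals among them, had their own liver as best match over the 300 most variable genes. This argues against mislabelling of the per-sample files as a whole. A further match, not among the planned tests, used 150 genes whose level per animal correlated between liver and muscle. The animal being matched was left out of the choice of genes. Of 27 animals 25 matched their own liver, 17 of the 19 MNR animals among them. This argues against mislabelling of the per-sample files of those animals. It does not decide for MNR files without such a match or for animals without a liver library. From the merged table, 0 of 19 MNR animals matched their own liver, consistent with columns of that table being mislabelled. Adipose libraries in turn best matched the muscle of their own number in 8 of 29 cases, and of their own glucose group in 28 of 29. A lack of shared signal is argued against, since one-to-one matching with muscle over genes of odd chromosomes and over genes of even chromosomes named the same animal for 22 of 29 libraries (3.76 expected within glucose groups, permutation p = 1e-05, the smallest that 100000 permutations can give). A candidate explanation is that animals were numbered in another order in adipose tissue. The correlation within file-name codes was 0.139 after matching against -0.0638 as labelled. The matching used the same expression data, so this rise is not independent of it and cannot decide the question.

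Heat shock genes were lower in intolerant than in control animals in each tissue. Library depth as a covariate left at least 97.8% of the score difference, which argues against depth as the whole cause. A score of clock genes left at least 86.0%. That score stands in for the time of collection only in part, so it cannot decide how much that time contributes. The heat shock scores of liver and muscle went together across 27 animals within groups (Pearson r = 0.725, Spearman rho = 0.664, permutation p = 1e-05 and 0.00024, the first the smallest that 100000 permutations can give; r = 0.631 without the 2 farthest animals; adjusted p = 0.00012 over 24 relations). A state of the whole animal at collection, such as handling or body temperature, may therefore contribute, as may a likeness of animals that share a file-name code. The permutations took animals as independent, while the correlation within codes over all genes was 0.141 in liver and 0.137 in muscle. An effect of the pregnancy or of glucose intolerance stays open and was not tested apart from these.

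In adipose tissue macrophage genes were higher and adipocyte genes lower in intolerant than in control animals. A lower share of adipocytes alone would raise the markers of every other cell type, yet the endothelial score differed by -0.174. That score did not pass over the lists. It passed in 1 of 17 tests that left out 1 animal (exact permutation adjusted p up to 0.114), so it argues only weakly against that share as the whole cause. The macrophage score difference was 0.920 without the libraries with Pax8 or Prm2 reads (exact permutation p = 0.00991, adjusted p = 0.0892, so the call ended without them), which argues against epididymal tissue as the whole cause. Between means per file-name code, with codes of the animal each library matched in muscle, it was 1.24, so sharing of codes does not remove the difference. The exact permutation p was 0.00303, the smallest that 7 against 4 codes can give (adjusted p = 0.0545). A list at that p cannot pass by itself, only where enough other lists have small p-values too. Macrophages entering the fat of intolerant animals, or a change in adipocytes themselves, stay open as hypotheses, not tested here.

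Other splits of the same animals into groups of the same sizes were drawn, 40 per comparison with the real one included. They take animals as independent, although animals share file-name codes, so they do not speak to an effect of the codes: with counts summed per code 0 genes passed in MNR liver, and with the codes of matched animals as a random block 0 in intolerant fat. No other split called as many genes in liver between MNR and control (7, highest other split 1, 1 of 40 splits as large). The same held in adipose tissue between intolerant and control (957, highest other 0, 1 of 40). Within that limit, both argue against chance. A share of 1 in 40 is the smallest that 40 splits can give and was not adjusted over the comparisons, so chance is not excluded. Other splits called as many genes in liver between tolerant and control (2, highest other 9, 4 splits as large). They also did in muscle between intolerant and control (2, highest other 2, 2 splits) and IFBG and control (1, highest other 1, 2 splits). In adipose tissue they did between MNR and control (1, highest other 305, 15 splits) and intolerant and tolerant (274, highest other 1306, 4 splits). The splits give no case against chance for these counts. Counts of 0 are reached by any split (40 of 40), which decides nothing, with a highest other of 0 (liver, intolerant against control), 2 (liver, IFBG against control), 2 (liver, intolerant against tolerant), 215 (muscle, MNR), 15 (muscle, tolerant), 2 (muscle, intolerant against tolerant), 589 (adipose, tolerant) and 0 (adipose, IFBG). Splits with 215, 305, 589 or 1306 genes point to a structure of the samples, whose source was not tested.

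Chance could not be excluded for any count of lists passing camera. In liver, 12 lists passed in each comparison, and 10 splits gave as many for MNR (highest other 16), 9 for intolerant (20), 18 for tolerant (17), 14 for IFBG (19) and 20 for intolerant against tolerant (20). In muscle 12, 13, 13, 13 and 17 lists passed, with 21, 19, 14, 14 and 12 splits as large and highest others of 19, 24, 21, 19 and 21 in the same order. In adipose tissue 20, 18, 16, 14 and 11 lists passed, with 3, 7, 5, 14 and 27 splits as large and highest others of 20, 25, 18, 22 and 22. For the tissue differences, 30 splits were drawn: chance could not be excluded for liver against muscle (1 gene, highest other 6; 2 splits) or muscle against adipose tissue (1, highest other 10; 6 splits). For liver against adipose tissue (0, highest other 430) the splits decide nothing, since all 30 reach a count of 0.

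The MNR effect on Ank3 differed by 1.06 between liver and muscle, and that on AK157302 by 0.49 between muscle and adipose tissue, both by an interaction term. With the animal as a block both calls were lost, for AK157302 only with the matched adipose animals. In 25 of 352 groups tested a sample stood far from the others, by the gap to its nearest neighbour as a share of the range; chance gives about 1 in 20 groups. In liver the share was 0.682 for Cyp3a57 and 0.609 for Zbtb16 (both intolerant animal 5, lowest) and 0.555 for Dym (tolerant animal 7, lowest). In muscle it was 0.832 for Gm13010 (control animal 6, lowest) and 0.655 (tolerant animal 2, highest), 0.548 for mt-Nd6 (control animal 7, lowest), 0.55 for Foxo3 (tolerant animal 5, highest) and 0.502 for Pdpk1 (intolerant animal 2, highest).

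In adipose tissue, intolerant animal 5 was highest for Ighg1 (0.627), Ighg2c (0.493), the heat shock score (0.574) and the T and NK cell score (0.511). Intolerant animal 9 was highest for Mmp14 (0.499), Prom2 (0.781), Cdh16 (1), Pou3f3 (1) and Pax8 (0.681) and lowest for Akt2 (0.634) and Adipoq (0.534), and intolerant animal 1 was lowest for Col8a1 (0.501). For Cdh16 and Pou3f3 animal 9 held only 0.206 and 0.412 CPM, with the other intolerant animals at 0 CPM. The share of 1 there reflects values at the floor. Among tolerant animals, animal 8 was highest for Ccdc69 (0.69), and animal 6 was highest for Rrm1 (0.631) and lowest for Slc2a4 (0.566). Among controls, animal 5 was highest for Robo4 (0.7) and animal 7 lowest for Ptx3 (0.657).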

How the results depend on the processing

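Omitting libraries by their marker reads, omitting each animal of both groups in the 2 adipose comparisons with many calls, the matched adipose numbering and the score permutation were chosen only after the results were seen. Of 228 alternative counts, 125 lay within 1.5 times the reported one and 103 moved. Of 3703 alternative values of 214 named genes and comparisons, 2702 kept their side of the threshold. Of these, called ones kept their direction and those never called stayed within their SE. A further 809 lost the call, 84 gained one, 103 that were never called moved by more than their SE, and 5 with a call in either fit reversed. Sign changes of values never called, such as Serpina3h in IFBG fat, were not counted as reversed. Adipose tissue had the fewest reads and the largest spread. The merged table could not be run for adipose tissue, since it holds ranks. The totals above include the merged muscle table, whose MNR columns hold counts of other MNR animals. Its comparisons of muscle glucose groups are therefore no test of the processing. The cause of each change below was not tested unless given.

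DESeq2 called 42, 32, 33 and 5 genes in liver (MNR, intolerant, tolerant and IFBG against control), 2, 78 and 6 in muscle (MNR, intolerant, tolerant), 56, 1607, 184 and 12 in adipose tissue, and 66, 10 and 13 for liver against muscle, liver against adipose and muscle against adipose tissue. RLE scaling gave 0 in IFBG muscle and 2 for liver against adipose tissue. Without a count filter there were 1 (MNR muscle), 0 (IFBG muscle), 402 (intolerant adipose) and 103 (intolerant against tolerant adipose). limma-voom with the code as a random block gave 2 (MNR liver), 1 (tolerant liver), 1 (intolerant muscle), 2 (IFBG muscle), 15 (MNR adipose), 433 (intolerant adipose) and 0 (intolerant against tolerant adipose), and without it 1 (tolerant liver), 2 and 1 (MNR and intolerant muscle), 11, 398 and 0 in those adipose comparisons. With the matched adipose numbering the block gave 0 and 0 for the last pair, and the animal as replicate block 0 for muscle against adipose tissue.

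Title numbers did not pair animals of different groups: the median correlation of same-numbered animals was -0.0032 in liver, 0.0179 in muscle and 0.0673 in adipose tissue, and 4 of 27, 3 of 29 and 5 of 29 correlated best with their own number. With the title number as a replicate block 0 genes were called in IFBG muscle and 5, 9, 5 and 18 in adipose tissue (MNR, intolerant, tolerant, intolerant against tolerant), and with the animal as a replicate block 0 for liver against muscle. The merged table gave 0 and 0 in intolerant and IFBG muscle. Of its 21 MNR muscle columns, all holding another animal's counts, 12 held those of another glucose group. These counts therefore cannot show whether the muscle calls depend on the processing. The first lane alone, with fewer reads, gave 1 in tolerant liver and 0 and 0 in those muscle groups. Both groups alone, with fewer animals to estimate the spread, gave 10 and 1 in intolerant and tolerant liver, 6 and 0 in intolerant and IFBG muscle and 0 for intolerant against tolerant fat. Counts summed per code gave 0 in MNR liver and 0 in MNR fat, and equal weights of the MNR groups 1 in MNR muscle.

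Leaving out control codes or animals in turn gave 0 to 8 genes in MNR liver, 0 to 0 in IFBG liver, MNR muscle and IFBG muscle, 0 to 1 in MNR fat, 0 to 1734 in intolerant fat, 0 to 11 in IFBG fat and 0 to 728 for intolerant against tolerant fat. Without intolerant animals 8 and 9 MNR fat had 3 calls. Without the libraries with Pax8 or Prm2 reads there were 5, 154 and 0 calls (MNR, intolerant, intolerant against tolerant fat), and without those with the most Alb reads 0, 19 and 0 in fat and 0 in IFBG muscle. Of 535 list tests 207 passed camera, 1 with the correlation estimated and 15 by exact permutation. Ighg1 between intolerant and tolerant fat went to -0.094 with DESeq2 and -0.042 without intolerant animal 5 (range over single animals left out -0.042 to 7.72), and without the libraries with Pax8 or Prm2 reads Krt18, Krt8 and Fads2 went to 0.71, 0.73 and 0.45.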

Other observations

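The correlations in this part were chosen only after the results were seen, and their permutations took animals as independent, although animals share file-name codes. Other lists of cell types and states moved in single comparisons without passing the exact permutation test. In intolerant liver, acute phase genes had 24 of 25 members below 0 (median -0.17, camera adjusted p = 0.002; adjusted p = 0.636 with an estimated correlation). In IFBG muscle, fibroblast genes had 18 of 21 above 0 (median 0.22; adjusted p = 0.693 with an estimated correlation). In intolerant fat, mesothelial genes had 12 of 12 members below 0 (median -0.63; adjusted p = 0.483 with an estimated correlation).

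Scores of circadian clock genes also went together in liver and muscle of an animal within groups (n = 27, Pearson r = 0.732, Spearman rho = 0.766, permutation p = 1e-05 and 2e-05, the first the smallest that 100000 permutations can give; r = 0.722 without the 2 farthest animals; adjusted p = 0.00012 over 24 relations). Heat shock scores of liver and adipose tissue had r = 0.161 (rho = 0.163, permutation p = 0.423 and 0.414, r = 0.236 without the 2 farthest, adjusted p = 0.534) with animals numbered as labelled. With animals matched they had r = 0.736 (rho = 0.742, permutation p = 2e-05 for both, r = 0.660 without the 2 farthest, adjusted p = 0.00016). The matching used the same expression data, so this value is not independent of it.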
